A study of Homo sapiens with 54 samples.

How the data were processed

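RNA was measured in 54 libraries of SW480 cells, a human colorectal adenocarcinoma line, that form 27 groups of 2 libraries. In 26 groups the cells had received an siRNA (a short double-stranded RNA that guides cleavage of a matching transcript) against 1 gene, and the CTRL group had received a control siRNA. Per the labels' protocols, 400000 cells were plated in 6-well plates, transfected with Lipofectamine and collected 72 hours later, and libraries were made with the Lexogen QuantSeq 3′ FWD kit, which reads the 3′ ends of polyadenylated transcripts. The labels do not say that the 2 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. The siRNA sequences, and whether an siRNA was a single duplex or a pool, are not given in the sources used here.

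The values analysed were raw read counts per gene symbol, as deposited by the authors in 1 table. Per the submitters' processing notes, the tools were STAR 2.7 and featureCounts 1.6.3 and the genome build was GRCh38. The annotation release, the strand setting, read trimming and any use of molecular identifiers are not given in the sources used here. The table listed 52871 symbols, of which 32113 had at least 1 count, and 42682 matched the RefSeq gene table of GRCh38.p14. It also held 5674 numbered copies of symbols, as genes on alternate loci have, with a mean of 0.0258% of counts. Reads that match both a gene and such a copy can be left uncounted, so that a symbol with a copy and a count of 0 is not evidence of absence; this applies to the targets CCL5 and MTMR9. Pseudogenes and other near-identical copies share reads with their parent genes, and their values are uncertain. Without a stated strand setting, counts of overlapping and antisense genes are uncertain.

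Total counts per library ranged from 3890909 to 5913631 (median 4662396), so that 3 counts, taken as the detection floor, correspond to 0.507 to 0.771 CPM (counts scaled to library size). Floors and counts cover counting error only, since reads without molecular identifiers are not independent molecules. Mitochondrial ribosomal RNA took 13.9% to 24.1% of counts. Pseudogenes took 0.694% to 1.11%, and the CTRL group had the highest mean share, 1.07%. No 2 libraries of a group agreed within sampling noise: the chi-square statistic per gene between them was 1.49 to 10.7.

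Differential expression was tested with edgeR 4.0.16 in R 4.3.3: TMM normalization, filterByExpr by group with a minimum count of 10, 1 coefficient per group, and the quasi-likelihood F test, with Benjamini-Hochberg adjustment over genes within a contrast and a threshold of 0.05. The filter kept 13579 genes. Targets with any count were kept whatever the filter said, which gave 13584 genes. All 54 libraries shared 1 estimate of the spread (27 residual degrees of freedom, prior degrees of freedom 21.3, common biological coefficient of variation 6.61%). Each siRNA group was compared with CTRL. Further contrasts compared each siRNA group with the mean of the other 25, the mean of the 26 siRNA groups with CTRL, and the 26 siRNA groups with each other in 1 F test. Standard errors of log2 fold changes were taken from the size of the fold change and its F statistic.

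Of 25 gene lists fixed before the data were examined, 20 had enough members to be tested, with camera from limma 3.58.1 on log2 CPM (prior count 2), at the preset inter-gene correlation of 0.01 and again with an estimated correlation. Adjustment ran over all 520 tests of lists and siRNAs. The lists covered epithelial, mesenchymal, G2/M, DNA replication, p53 target, interferon-stimulated, NF-kB target, Wnt target, cholesterol synthesis, amino acid and unfolded protein response, ribosomal protein, ribosome biogenesis, nuclear and mitochondrially encoded respiratory chain, mitochondrial ribosome, hypoxia and glycolysis, colon differentiation, matrix, actin cytoskeleton, FOXO and insulin feedback, centriole and RNA interference genes, and markers of fibroblasts, leukocytes and endothelium. Similarity of profiles was Pearson's r of log2 CPM centred on the mean of the group means, over the 1000 genes with the smallest p in the F test among siRNA groups.

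Genes named in the text were chosen by a rule set before the data were examined. They were the 26 targets; per siRNA up to 2 higher and 2 lower genes (up to 8 each for the 4 siRNAs with most) with the largest fold change among genes past the threshold against CTRL and against the other siRNA groups, the same way in both, with a mean of at least 10 CPM and with both siRNA libraries outside the range of the 2 CTRL libraries; the 10 higher and 10 lower genes of the average contrast; and 2 to 4 members with the smallest p of lists that passed. Y-linked genes and XIST were left out. Some genes that the rule names are not reported here.

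The test was checked on simulated counts of all 54 libraries over 13584 genes. Each gene had 1 mean pooled over all libraries, and genes varied independently. Changes were planted in the PLK4 libraries, which were tested against CTRL. The test recovered 34 of 67 genes changed 1.5-fold, 46 of 67 changed 2-fold and 61 of 66 changed 4-fold, and 6 of its 147 calls (4.08%) were false. With camera, simulated for the DDR2 libraries against CTRL, 11 of 200 unchanged lists had an unadjusted p under 0.05 and 0 passed after adjustment. A list of 25 genes raised 1.3-fold passed. Because the simulated genes were independent, this cannot show how the preset correlation serves lists whose genes vary together. Because all contrasts share the 2 CTRL libraries, 8 sets of unchanged groups were simulated, in which CTRL was drawn anew from the same pooled means. These sets therefore hold no deviation of the real CTRL libraries, no batch and no correlation between genes.

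The alternatives were DESeq2's size factors within edgeR, DESeq2 1.42.0, no filter and a stricter filter on low counts, the replicate number as a block, only the 4 libraries of a comparison, a test against a 1.2-fold change, the other siRNA groups as reference, and leaving out each library in turn. The share of pseudogene counts as a covariate, gene list tests without each CTRL library, and the count of lower targets in the 1.2-fold test were chosen after seeing the data. Matches of 7 bases were sought in 3′ UTRs of the GENCODE v29 transcripts on GRCh38, with Python 3.11.15, for 7974 of 8463 genes (94.2%) with a mean of at least 10 CPM. That search found 5 of 5 planted 7-mers first in simulated data of 7974 genes.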

Results

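SW480 cells are an established line from a human colorectal adenocarcinoma. The series asked how the transcriptome of these cells changes when each of 26 genes proposed to promote metastasis is silenced, and which of the 26 silenced states resemble each other. Each gene was targeted with siRNA, a CTRL siRNA served as the reference, and polyadenylated RNA was counted from its 3′ ends 72 hours after transfection in 2 libraries per group. The 54 libraries held 3890909 to 5913631 counts each (median 4662396). Fold changes are log2 values from edgeR with their standard error (SE), from 2 siRNA libraries against 2 CTRL libraries unless stated otherwise, and all calls are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at a threshold of 0.05.

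The target transcripts were examined first, as a check of the labels. The largest reduction was that of CMTM6, a membrane protein that stabilises PD-L1 (chromosome 3, 32481312 to 32503408, GRCh38), which fell from 128 ± 7.98 CPM in CTRL (SD, n = 2) to 4.81 ± 0.413 CPM (SD, n = 2), a log2 fold change of −4.73 (SE 0.17, adjusted p = 5e-27 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). MRPL24, a protein of the mitochondrial ribosome (chromosome 1, 156737303 to 156741590), fell from 61.8 ± 2.48 to 6.42 ± 1.26 CPM (SD, n = 2 each). CORO1B, an actin regulator, and RELB, an NF-kB subunit, lost 84.7% and 82.4% of their CTRL level. PLK4, the kinase that starts centriole duplication, lost 80.9%, and the growth factor receptors IGF1R and INSR lost 80.0% and 68.1%.

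Of the 26 targets, 20 had at least 1 count in the 54 libraries and were kept in the fit, among them PLG and PRSS37 with 0 counts in their own and the CTRL libraries. In their own siRNA group 13 were lower. The same number was lower against the other 25 siRNA groups, and 14 passed when p-values were adjusted over the list alone, with GPR173 added. Reductions among the 13 ranged from 44.7% for MEF2D to 96.2% for CMTM6, with a median of 78.0%. In 12 of the 13, the siRNA's own libraries were the lowest 2 of all 54; the exception was MEF2D. The call for MEF2D was lost without CTRL replicate 2 or without its own replicate 1, and that for MST1R without CTRL replicate 1 (adjusted p = 0.0650, 0.0663 and 0.0501 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

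The other 13 targets were too low for a comparison or did not pass. TMEM164 was at 2.08 CPM against 3.30 in CTRL and GPR173 at 0.885 against 2.62 (adjusted p = 0.312 and 0.147 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). DDR2, OR10A5 and GPR56, listed as ADGRG1, had at most 3 counts in any of their own or the CTRL libraries, so that a reduction was not detectable at this depth. CCL5, PLG, MYH7, ODAM, FGF8, SPACA1, MTMR9 and PRSS37 had 0 counts in both CTRL libraries, and for CCL5 and MTMR9, which have numbered copies in the table, the zeros are not evidence of absence. For these 11 targets the data do not check the labels.

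**Figure D1:**
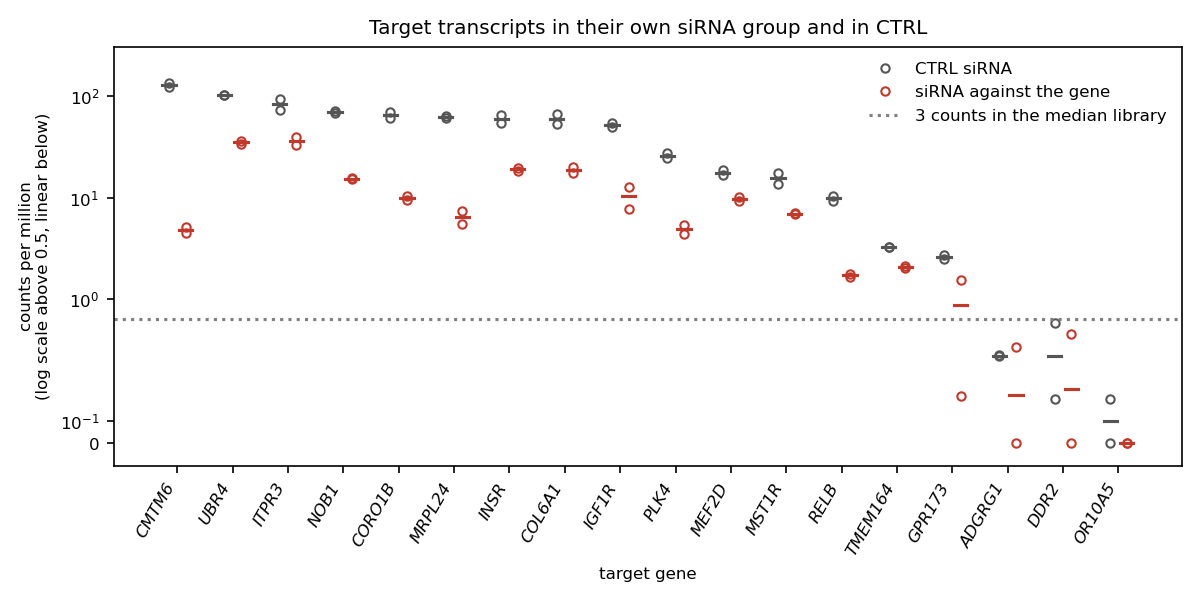
CPM, counts scaled to library size (log scale above 0.5, linear below) of each target gene with counts in CTRL or in its own siRNA group; open circles are single libraries, bars the mean of 2, grey for CTRL and red for the siRNA against the gene, and the dotted line marks the median over libraries of the level of 3 counts. CMTM6 shows the widest gap, from 128 to 4.81 CPM, and the libraries of OR10A5, DDR2 and ADGRG1 lie below the dotted line, several of them at 0.

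The siRNAs differed widely in how many genes they changed. The siRNA against MEF2D, a transcription factor, changed most, with 1989 genes higher and 2251 lower than CTRL, and that against ODAM fewest, with 37 of 143 genes higher and the others lower. Those against OR10A5, CORO1B and INSR followed MEF2D with 3384, 3283 and 3155 genes. With the share of pseudogene counts as a covariate, OR10A5 (2724 genes) and CORO1B (2366) came before MEF2D (2226). The median over the 26 siRNAs was 1607 genes, and changes of at least 2-fold numbered 21 to 1011 per siRNA (median 256). Across the 26 contrasts 3413 genes were never called, while 166 were higher and 221 lower in 13 or more. Simulated unchanged groups that shared 2 simulated CTRL libraries gave 0 such genes. They hold no deviation of the real CTRL libraries, so that this 0 does not test it. Part of the excess may come from the shared controls, which are too few to split. The counts also differed along the deposited order of samples, which ends with CTRL. From GPR173 onward they were 143 (ODAM) to 2216 (CMTM6), and before it 528 (PLG) to 4240 (MEF2D). This split was chosen after the counts were seen, and nearness to CTRL in that order was not separated from effects of the siRNAs. The counts rested on few libraries: the median was 929.5 or 896 genes without CTRL replicate 1 or 2, and for CORO1B the count was 2058 without CTRL replicate 1, 1677 without its own replicate 2 and 154 when only the 4 libraries of that comparison were fitted. The count for ODAM was 54 or 22 without CTRL replicate 1 or 2 and 12 or 25 without its own replicate 1 or 2, that for OR10A5 was 2220 without its own replicate 1, and that for INSR was 1969 without CTRL replicate 2 and 2021 or 1987 without its own replicate 1 or 2.

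**Figure D2:**
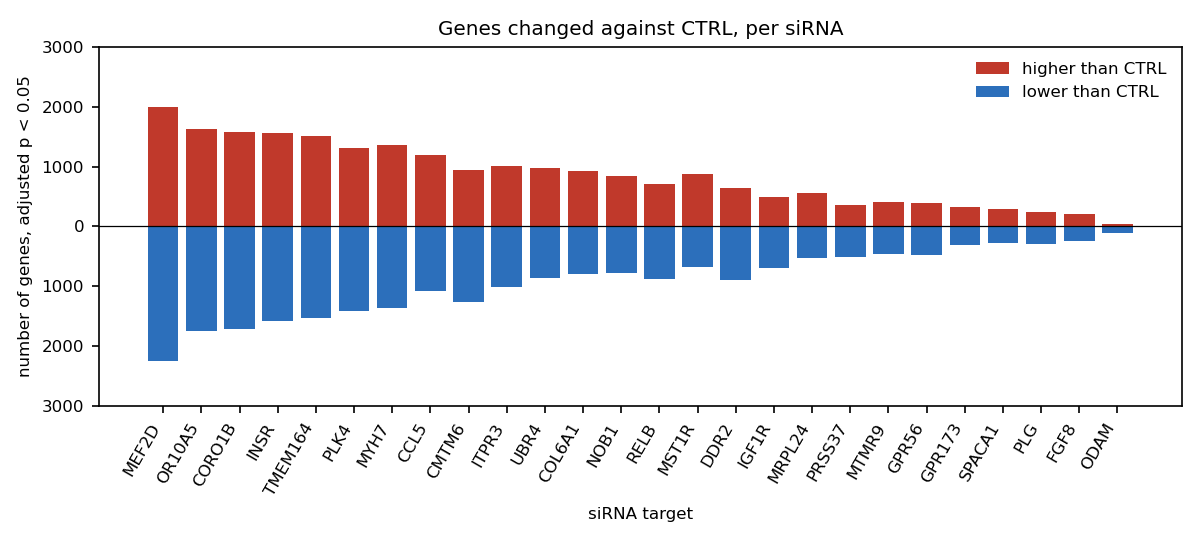
Number of genes (vertical axis) higher, in red, and lower, in blue, than CTRL for each siRNA (horizontal axis, ordered by the total), at an adjusted p under 0.05. Totals fall from 4240 for MEF2D to 143 for ODAM.

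After the siRNA against MEF2D, proliferation genes fell together. All 25 G2/M genes were lower (camera adjusted p = 4.46e-21), among them UBE2C, which tags mitotic cyclins for degradation, at −1.5 (SE 0.12), and HMMR, a spindle protein, at −1.39 (SE 0.09). Of 23 DNA replication genes 19 were lower, with the sliding clamp PCNA at −1.57 (SE 0.14) and the nucleotide synthesis enzyme RRM2 at −0.80 (SE 0.08). The amino acid and unfolded protein response list moved up, with 15 of 23 members higher and 2 lower; the chaperones HSP90B1 and CALR rose by 0.54 and 0.61, whereas HSPA5, the main chaperone of the endoplasmic reticulum, fell by 0.59. Epithelial genes moved up as a list (10 of 19 higher, 1 lower), with the laminin chain LAMB3 at 1.21. Among Wnt targets the antagonist DKK4 was at −3.65 (SE 0.18), TCF7 at −1.91 and cyclin D1 (CCND1) at −1.5, although 7 of 21 members were lower and 2 higher. That list's call was lost with an estimated correlation (adjusted p = 0.0568 by camera). Single genes with large rises were BIRC3, an inhibitor of apoptosis, at 2.18, the pregnancy glycoprotein PSG1 at 2.17, the peptidase KLK10 at 1.93 and the folate receptor FOLR1 at 1.80. OAT, a mitochondrial aminotransferase, fell by 2.7 and SDHD, a subunit of succinate dehydrogenase, by 2.38. Against the other siRNA groups BIRC3 was at 1.13 and SDHD at −1.12, PSG1 at 2.12, KLK10 at 1.69, FOLR1 at 1.54 and OAT at −1.86.

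Proliferation genes moved in other groups too, in both directions. G2/M genes were lower after the siRNAs against NOB1, a ribosome assembly nuclease (19 of 25 lower, none higher), TMEM164 (18 of 25) and MTMR9 (7 of 25), with camera adjusted p = 7.69e-16, 1.51e-12 and 6.73e-10. AURKB, a mitotic kinase, was at −0.67 with NOB1, UBE2C at −1.07 with TMEM164, and the cell cycle kinase CDK1 at −0.55 with MTMR9. DNA replication genes fell with TMEM164 (16 of 23), NOB1 (14 of 23) and IGF1R (8 of 23), where RRM2 was at −0.72 with TMEM164 and −0.44 with IGF1R, and the transcription factor E2F1 at −0.88 with NOB1. They rose with OR10A5 and ITPR3, 9 of 23 members each, with RFC3 at 0.71 and MCM3 at 0.62 with OR10A5 and RRM2 at 0.47 with ITPR3. With GPR56, 4 of 25 G2/M genes were higher, including TPX2 at 0.36 and MKI67 at 0.34. The call for MKI67 was lost without GPR56 replicate 2 (adjusted p = 0.0752 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Over all siRNAs the G2/M list was lower in 11 and higher in 4, and the DNA replication list lower in 9 and higher in 3. With an estimated correlation these became 6, 1, 6 and 2. At the preset correlation, 6, 4, 6 and 3 of them also passed the same way against the other siRNA groups.

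Stress and sterol genes moved in several siRNA groups. With UBR4, a ubiquitin ligase, 13 of 23 amino acid and unfolded protein response genes were higher and 3 lower (camera adjusted p = 9.64e-09): the cystine transporter SLC7A11 rose by 2.32 (SE 0.21), the pseudokinase TRIB3 by 1.53 and the serine synthesis enzyme PHGDH by 1.17. With CMTM6, 13 of 23 were higher and 2 lower, with the transcription factor ATF3 at 2.36 (SE 0.24), TRIB3 at 1.59, PPP1R15A, a phosphatase subunit of the stress response, at 1.51, and HSPA5 at 0.77. This list was higher in 4 siRNA groups, with MEF2D and OR10A5 as the others, and lower in 2, and with an estimated correlation 3 and 0 held; the call for OR10A5 was lost (adjusted p = 0.0771 by camera). Cholesterol synthesis genes were higher in 12 siRNA groups and lower in 2, of which 5 and 2 held with an estimated correlation. Of the calls at the preset correlation, 5 were also higher and 2 also lower than in the other siRNA groups. Among the 12 were CORO1B (16 of 22 members higher), NOB1 (13 of 22) and FGF8 (4 of 22). HMGCS1, an early enzyme of the pathway, rose by 1.06, 1.43 and 0.55 in these 3 groups, and by 0.96 with TMEM164 and 0.95 with PLK4, 2 values chosen after they were seen. The same list was lower with CMTM6 (10 of 22 lower, none higher), where the sterol carrier STARD4 was at −1.01. It was also lower with UBR4 (7 lower, 1 higher), where the sterol oxidase MSMO1 was at −0.63. The call for MSMO1 was lost without UBR4 replicate 2, where it was at −0.48. Against the other siRNA groups HMGCS1 did not pass with FGF8 (adjusted p = 0.119 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Camera adjusted p-values were 1.55e-10 for CORO1B, 1.47e-11 for NOB1, 0.000178 for FGF8, 1.15e-06 for CMTM6 and 0.000202 for UBR4. These rest on the spread in all 54 libraries, whereas the 2 CORO1B libraries differed most from each other (chi-square per gene 10.7).

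Epithelial and mesenchymal genes bear on the metastasis question of the series. After the siRNA against PLK4, 13 of 19 epithelial genes were higher and 1 lower (camera adjusted p = 1.5e-08), with E-cadherin (CDH1) at 1.34 (SE 0.19), the keratins KRT19 and KRT18 at 0.93 and 0.78 and the adhesion molecule EPCAM at 0.87. In the same cells 11 of 21 mesenchymal genes were lower and 1 higher (camera adjusted p = 0.000256), with fibronectin (FN1) at −1.45 (SE 0.17) and vimentin (VIM) at −0.53. Both lists were lower with ITPR3, a calcium channel of the endoplasmic reticulum, and with CMTM6. With ITPR3, EPCAM was at −0.81, LAMB3 at −1.37, S100A4 at −1.48 and FN1 at −1.09, while the desmosomal gene DSP rose by 0.43. With CMTM6, ST14 was at −0.85, FN1 at −1.12 and SPARC at −0.66. Mesenchymal genes were also lower with RELB, OR10A5 and DDR2: the receptor kinase AXL was at −1.36 with RELB and −1.53 with OR10A5. Epithelial genes were lower with MST1R and MTMR9, where the splicing regulator ESRP1 was at −1.60 and −1.24. The mesenchymal list was lower in 6 siRNA groups and higher in none, and all 6 calls held with an estimated correlation. The epithelial list was higher in 5 and lower in 5, and 2 and 4 of these held.

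Genes of the translation machinery moved in both directions. With IGF1R, 20 of 29 ribosomal protein genes were lower and none higher (camera adjusted p = 1.96e-16), with RPL5 at −0.55 and RPL23 at −0.52, and with MYH7 21 of 29 were lower, with RPLP0 at −0.47. They were higher with ITPR3 and PLK4, 13 of 29 each, where RPL18 rose by 0.44 and 0.51. With COL6A1, 7 were higher and RPL27 was at −1.34 (SE 0.09), opposite to the list, whose call was lost with an estimated correlation (adjusted p = 0.104 by camera). Ribosome biogenesis genes were higher with CMTM6 (20 of 28) and MST1R (15 of 28): the nucleolar protein GNL3 rose by 0.81 with CMTM6, and nucleolin (NCL) and nucleophosmin (NPM1) by 0.67 and 0.58 with MST1R. With MYH7 11 of 28 were lower, including the pseudouridine synthase DKC1 at −0.49. Mitochondrial ribosome genes were lower with INSR (13 of 26), where MRPS9 was at −2.06 (SE 0.12), and with TMEM164 (11 of 26), where MRPL3 was at −1.07. Over all siRNAs the ribosomal protein list was higher in 10 and lower in 8, of which 6 and 4 held with an estimated correlation. Ribosome biogenesis genes were higher in 13 and lower in 3, of which 5 and 2 held. Of the 13 higher, 6 were also higher than in the other siRNA groups, and the 3 lower were also lower. Mitochondrial ribosome genes were lower in 7, of which 4 held, and higher with PLK4, CCL5 and CMTM6, where the calls were lost (adjusted p = 0.158, 0.109 and 0.191 by camera with an estimated correlation).

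The inflammatory and Wnt target lists each passed in 1 direction only. NF-kB targets passed as higher in 13 siRNA groups and as lower in none, of which 9 held with an estimated correlation and 5 were also higher than in the other siRNA groups. With ITPR3, 7 of 15 were higher, with the inhibitor NFKBIA at 0.96 and TNIP1 at 0.82. BIRC3 was at 2.58 (SE 0.21) with MYH7 and 2.54 (SE 0.21) with CCL5. Wnt targets passed as lower in 11 groups and as higher in none; 9 held with an estimated correlation and 5 were also lower than in the other siRNA groups. DKK4 was at −2.18 with DDR2, −1.85 with RELB and −1.08 with UBR4, the antagonist NKD1 at −1.21 with CMTM6, and APCDD1 between −0.75 with UBR4 and −0.39 with RELB. Some members went against their list: CCND1 was at 0.41 with GPR56, LEF1 at 0.49 with CCL5, and the NF-kB target SOD2 at −0.89 with CORO1B. These 3 values were chosen after they were seen. Against the other siRNA groups DKK4 did not pass with UBR4 (adjusted p = 0.292 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The 2 CTRL libraries enter every one of these counts, and both lists also passed in these directions in the average of all siRNA groups against CTRL, where the calls were lost with an estimated correlation (adjusted p = 0.0614 and 0.0555 by camera).

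Matrix genes were higher with MYH7 (11 of 17, camera adjusted p = 2.82e-07) and INSR (8 of 17), with the laminin chain LAMC1 at 0.97 and 0.95, and lower with CMTM6 (7 of 17), with the collagen COL4A2 at −0.96. Over all siRNAs they were higher in 10 and lower in 1, of which 8 and 1 held with an estimated correlation. Of the 10 higher, 5 were also higher than in the other siRNA groups, and the 1 lower was also lower. FOXO and insulin feedback genes were higher with TMEM164 (11 of 22 higher, 1 lower) and PRSS37 (6 of 22), where SESN3, a stress-induced inhibitor of mTORC1, rose by 1.83 and 0.91. This list was higher in 5 siRNA groups, of which 3 held with an estimated correlation, and lower with DDR2 (4 of 22 lower, 1 higher), where the call was lost (adjusted p = 0.146 by camera with an estimated correlation). SESN3 was there at −1.01, a value chosen after it was seen. For GPR56, an adhesion receptor, a reduction of the target was not detectable at this depth. With its siRNA the actin cytoskeleton list was higher (7 of 21 higher, 1 lower, camera adjusted p = 7.35e-05). There the myosin light chain MYL9 rose by 2.62 (SE 0.19) and gamma-actin (ACTG1) by 1.04, while beta-actin (ACTB) fell by 0.78. With GPR173 the list was lower (3 of 21), and both calls held with an estimated correlation.

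Single genes also changed strongly with the siRNAs against OR10A5, CORO1B and INSR, next to MEF2D in extent. Of these targets, OR10A5 was too low for a reduction to be detectable. With OR10A5, an olfactory receptor, the reductase DHRS2 was at 1.89 (SE 0.13), the glucocorticoid-induced TSC22D3 at 1.53 and the aminotransferase GPT2 at 1.37, whereas ARL6IP6 was at −3.48 (SE 0.25), the glycosyltransferase GALNT7 at −2.98, annexin A1 (ANXA1) at −2.15 and the vesicle protein VAMP3 at −2.10. With CORO1B, the glucose transporter SLC2A3 was at 1.55 (SE 0.06), the interleukin receptor IL6R at 1.47 and stratifin (SFN) at 1.43, and the keratin KRT5 was at −2.13 (SE 0.13). The 2 CORO1B libraries differed more from each other than those of any other group (chi-square per gene 10.7), with SFN at 261 ± 93.3 and KRT5 at 193 ± 77.2 CPM (SD, n = 2 each), whereas the SE rests on the spread in all 54 libraries. Without CORO1B replicate 1 or 2, KRT5 was at −2.62 or −1.78 and SFN at 1.76 or 1.01. With INSR, SLFN5 was at 1.97 (SE 0.11), the R-spondin receptor LGR6 at 1.92 and SESN3 at 1.62. DHRS2 was there at −2.18 (SE 0.21), opposite to its direction with OR10A5, the inflammasome adaptor PYCARD at −1.93 and the mitochondrial kinase DGUOK at −1.81. Some of these genes moved alike elsewhere, with ANXA1 at −2.68 with ITPR3, IL6R at 1.14 with SPACA1 and ARL6IP6 at −1.40 with PLG. For IL6R with SPACA1 the call was lost without CTRL replicate 2, where it was at 0.97. Further single genes were the secreted signal WNT9A, at 2.04 with CCL5, IGFBP3, a binding protein of insulin-like growth factors, at −2.95 with CMTM6, NRP1 at 1.23 and PDGFB at −1.43 with MST1R, and the centriole gene CETN2 at −2.35 with IGF1R.

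**Figure D3:**
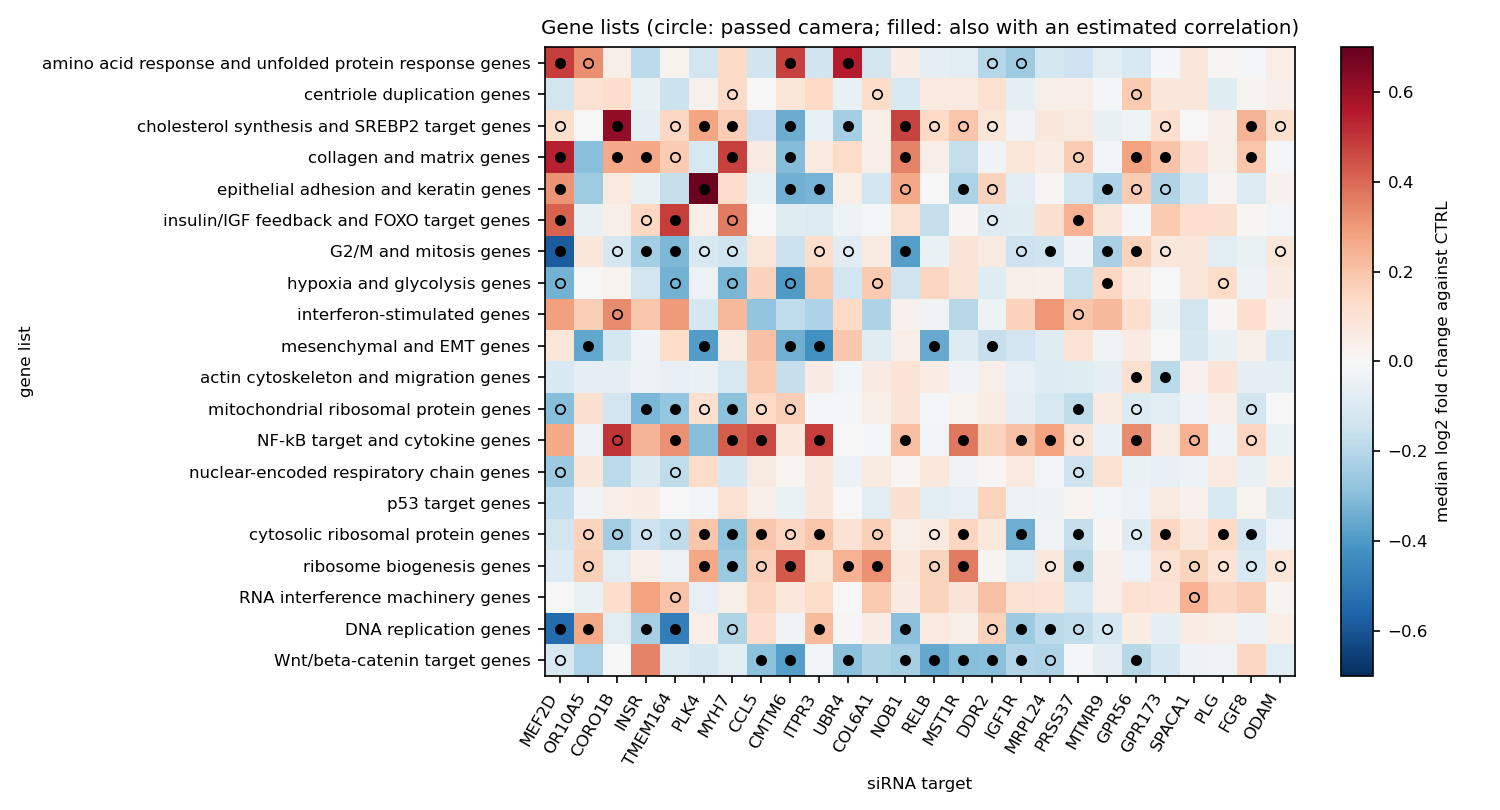
Median log2 fold change against CTRL (colour) of each gene list (vertical axis) for each siRNA (horizontal axis, ordered by the number of genes changed); a circle marks a list that passed camera at an adjusted p under 0.05 and a filled circle one that also passed with an estimated correlation. Of 520 tests 167 passed, and 91 with an estimated correlation.

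Calls of the remaining lists were mostly lost with an estimated correlation. The p53 target list passed in 0 of 26 siRNA groups with camera, at either correlation, and 1 group had an unadjusted p under 0.05, 0 with an estimated correlation. As lists, interferon-stimulated genes were higher with CORO1B and PRSS37, centriole genes with GPR56, COL6A1 and MYH7, and RNA interference genes with TMEM164 and SPACA1, and nuclear respiratory chain genes were lower with MEF2D, TMEM164 and PRSS37, but these calls were lost with an estimated correlation. Camera adjusted p with an estimated correlation was 0.168 and 0.110 for CORO1B and PRSS37, 0.0745, 0.128 and 0.186 for GPR56, COL6A1 and MYH7, 0.0502 and 0.0568 for TMEM164 and SPACA1, and 0.255, 0.363 and 0.263 for MEF2D, TMEM164 and PRSS37. With PRSS37, IFIT3 was at 1.21 and IFIH1 at 0.73. The call for IFIT3 was lost without CTRL replicate 1 or PRSS37 replicate 1 (adjusted p = 0.103 and 0.221) and that for IFIH1 without CTRL replicate 2 or PRSS37 replicate 2 (adjusted p = 0.132 and 0.130), by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Hypoxia and glycolysis genes were higher with MTMR9, PLG and COL6A1 and lower with MEF2D, TMEM164, MYH7 and CMTM6, against CTRL and against the other siRNA groups. Only the call for MTMR9 held with an estimated correlation, where camera adjusted p was 0.0290, 0.217, 0.196, 0.0502, 0.0745, 0.142 and 0.0568 in this order. Markers of fibroblasts, leukocytes and endothelium were near absent, with 2, 2 and 1 members tested and at most 7.48 CPM in CTRL (COL1A1). Of 25 colon differentiation genes 3 could be tested, and the 13 mitochondrially encoded protein genes were not analysed here.

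The average of the 26 siRNA groups differed from CTRL by 1078 genes, 405 higher and 673 lower. Simulated unchanged groups, which hold no deviation of the real CTRL libraries, gave at most 1. BIRC3 was at 1.09 (SE 0.18), PGM2L1, a sugar phosphate enzyme, at 0.84 (SE 0.09), the semaphorin receptor NRP1 at 0.61 and the cell cycle inhibitor CDKN1B at 0.60. PRRG3 was at −1.78 (SE 0.23), the cell cycle regulator RGCC at −1.33, the transcriptional corepressor ATN1 at −1.31 and SDHD at −1.3. DKK4 was at −0.90 and HMGCS1 at 0.40. Of the 10 genes with the largest falls, RPL13AP7, RPL23AP42, RPS20P2, EEF1A1P6 and RPL18AP3 are processed copies of translation genes, and 100 of 646 pseudogenes were lower and 3 higher. The share of counts on pseudogenes was highest in CTRL, 1.07%, against 0.704% to 0.986% in the siRNA groups. With that share as a covariate the count fell to 133 genes, and without CTRL replicate 1 or 2 it was 309 or 228. PRRG3 and the 5 copies named were among the calls lost with the covariate, where PRRG3 was at −0.82 (adjusted p = 0.163 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and EEF1A1P6 was also lost without CTRL replicate 1 (adjusted p = 0.0594). The NF-kB, cholesterol, matrix and ribosome biogenesis lists were higher and the Wnt and G2/M lists lower in this contrast, and all 6 calls were lost with an estimated correlation (adjusted p = 0.0614, 0.0907, 0.0772, 0.248, 0.0555 and 0.0907 by camera).

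The siRNA groups differed widely from each other: 10841 of 13584 genes (79.8%) differed among the 26 groups in the F test that leaves CTRL out. Simulated unchanged groups, which hold no batch, gave at most 4. The 2 libraries of each of the 27 groups were each other's nearest, with r between them of 0.730 to 0.971 across the 1000 genes with the smallest p in that F test, which were thus chosen for differing between groups and are not independent replicates. Across all 13584 genes the 2 libraries of each group were again each other's nearest, but r between them was only 0.215 to 0.698 (median 0.369), and r between libraries of different groups reached 0.293. Between groups r ranged from −0.465 for PLK4 and MYH7 to 0.489 for DDR2 and RELB, with a median of −0.0316. In 8 of 351 pairs all 4 correlations between their libraries exceeded 0.3. CTRL was closest to ODAM, the siRNA with fewest changed genes. Fold changes against the shared CTRL correlated with a median r of 0.396 between siRNAs, against 0.474 for simulated unchanged groups, and their median covariance was 0.0923 against 0.0524, a difference of 0.0398.

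**Figure D4:**
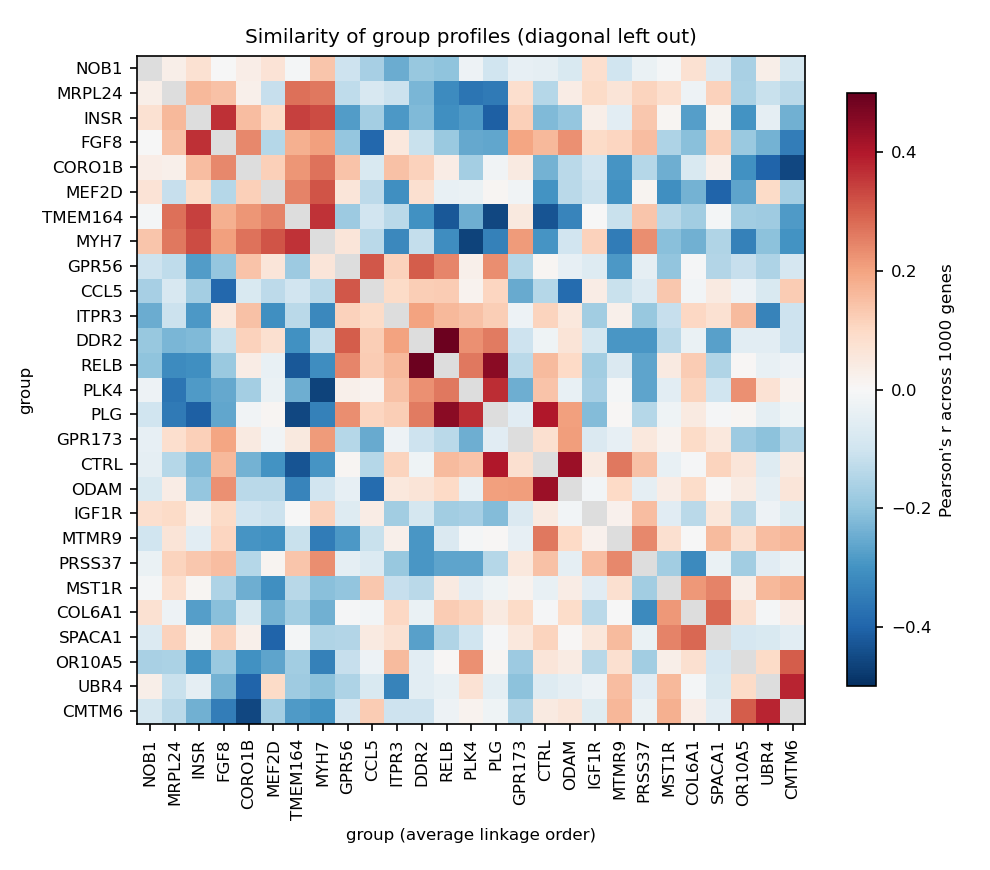
Pearson's r (colour) between the mean profiles of the 27 groups, on both axes in the order of average linkage clustering, over 1000 genes centred on the mean of the groups; the diagonal is left out. Values run from −0.465 to 0.489.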

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

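The pseudogene share as a covariate, gene list tests without a CTRL library, and the count of targets in the test against a 1.2-fold change were chosen after the data were seen. The same 13 targets were lower in each of the 9 settings that left out no replicate. Without 1 library, calls were lost only for MEF2D or MST1R, as given above. Genes differing among siRNA groups numbered 9504 to 11688 over the refits with other size factors, other filters, the block, the covariate or DESeq2. The remaining settings were not run for this count. Every group's libraries were each other's nearest in the similarity settings tried. No called pair of named gene and siRNA changed direction. With the covariate 24 of 303 pairs lost the call, and in the test against a 1.2-fold change, which covered fewer pairs, 18 lost it and 255 kept it. With the replicate number as a block, the counts were 1070 genes for the average siRNA group, 1598.5 for the median siRNA and 10811 among siRNA groups. With that block 166 tests of lists and siRNAs passed. The numbers did not pair the libraries (correlation of same-numbered deviations −0.138 to 0.180, median −0.0018, above 0.1 in 6 of 351 pairs of groups).

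The average siRNA group differed by 133 genes with the covariate and by 309 or 228 without CTRL replicate 1 or 2. The median per siRNA was 868 with the covariate, 394.5 against a 1.2-fold change, which is stricter by construction, 929.5 or 896 without CTRL replicate 1 or 2, and 896 to 1607 over all libraries left out in turn. Of 520 tests of lists and siRNAs, 91 passed with an estimated correlation, and 148 or 160 without CTRL replicate 1 or 2. Tested against a 1.2-fold change, the genes changed were 995 for PLK4, 433 for DDR2, 218 for GPR56, 398 for RELB, 2345 for MEF2D, 691 for CCL5, 1523 for CORO1B, 652 for ITPR3, 60 for PLG, 1332 for INSR, 518 for UBR4, 300 for MST1R, 376 for COL6A1, 1559 for OR10A5, 1206 for TMEM164, 978 for MYH7, 93 for GPR173, 391 for NOB1, 156 for MRPL24, 13 for ODAM, 326 for IGF1R, 716 for CMTM6, 29 for FGF8, 87 for SPACA1, 156 for MTMR9 and 138 for PRSS37. With the covariate they were 1216 for PLK4, 628 for DDR2, 285 for GPR56, 976 for RELB, 2226 for MEF2D, 1256 for CCL5, 2366 for CORO1B, 109 for PLG, 1799 for INSR, 771 for UBR4, 825 for MST1R, 878 for COL6A1, 2724 for OR10A5, 1838 for TMEM164, 1341 for MYH7, 624 for MRPL24, 15 for ODAM, 158 for FGF8 and 199 for SPACA1. Against the other 25 siRNA groups they were 3123 for ITPR3, 1606 for PLG, 1280 for GPR173, 2612 for NOB1, 501 for ODAM, 2136 for IGF1R, 1156 for FGF8, 2590 for MTMR9 and 2471 for PRSS37. With only the 4 libraries of a comparison they were 1409 for GPR56, 154 for CORO1B, 1273 for PLG, 495 for ODAM, 1290 for SPACA1, 1461 for MTMR9 and 1433 for PRSS37, and with no filter on low counts 255 for ODAM. Except for the 1.2-fold test, the cause was not tested.

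Without 1 library of CTRL or of the siRNA, where fewer libraries enter and a lone library is assumed to vary like the other groups, the genes changed ranged over 1485 to 1881 for PLK4, 602 to 904 for DDR2, 259 to 521 for GPR56, 548 to 1142 for RELB, 1094 to 1419 for CCL5, 1677 to 3854 for CORO1B, 882 to 1444 for ITPR3, 84 to 202 for PLG, 1969 to 2175 for INSR, 742 to 1284 for UBR4, 758 to 986 for MST1R, 677 to 1249 for COL6A1, 2220 to 2382 for OR10A5, 1680 to 2221 for TMEM164, 1684 to 1842 for MYH7, 234 to 387 for GPR173, 799 to 1059 for NOB1, 263 to 991 for MRPL24, 12 to 54 for ODAM, 567 to 775 for IGF1R, 1137 to 1538 for CMTM6, 73 to 529 for FGF8, 177 to 267 for SPACA1, 324 to 484 for MTMR9 and 282 to 485 for PRSS37. Only targets near the detection floor changed sign, and these had not passed: log2 fold changes were between −3.98 and 0.30 for DDR2, −3.98 and 0.13 for ADGRG1, and −3.06 and 0.00 for OR10A5 when 1 library was left out, with DDR2 at 0.16 without CTRL replicate 1 and 0.30 without its own replicate 1, and ADGRG1 at 0.13 without GPR56 replicate 2. Depth limits these targets, at 3 counts or fewer per library.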

Other observations

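The tests of loss of the target, of siRNAs with and without a detected target, of seed-like matches, of microRNA sites, of the CTRL libraries' own deviation and of the deposited order were chosen after the result was seen.

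Targets of the panel also differed in groups treated with other siRNAs, against CTRL and against the other siRNA groups. RELB was higher in 8 such groups and lower in none, at 1.14 with CORO1B (log2, SE 0.24), 1.11 with MEF2D (SE 0.24) and 1.02 with MYH7 (SE 0.25). COL6A1, a chain of collagen VI, was higher in 7, such as 0.70 with INSR (SE 0.12) and 0.64 with PLK4 (SE 0.11), and lower in 2, at −0.74 with CMTM6 (SE 0.13) and −0.44 with MRPL24 (SE 0.12). PLK4 was at −1.06 with MEF2D (SE 0.21), and IGF1R at −0.77 with UBR4 (SE 0.16) and −0.67 with CMTM6 (SE 0.15).

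The 6 siRNAs whose target had 0 counts in CTRL and has no numbered copy changed a median of 552 genes against CTRL (143 to 2719) and 1381 against the other siRNA groups, but 236.5 or 194.5 without CTRL replicate 1 or 2, 170 or 243.5 without replicate 1 or 2 of each siRNA, 178.5 with the pseudogene share as a covariate and 73.5 in the test against a 1.2-fold change. This count cannot decide on loss of the target transcript as a cause, since it is the pattern itself. The 15 siRNAs whose target was above 3 counts in both CTRL libraries changed a median of 1827. The two-sided exact rank-sum p was 0.00623 against the 6 and 0.0274 against all 11 others (Benjamini-Hochberg adjusted 0.0125 and 0.0274). Of the 6, all but PLG lay in the later part of the deposited order of samples, which ends with CTRL. Most of the 15 lay in the earlier part. The rank-sum test cannot tell detection of the target apart from that order, and it does not bear on the cause in the 6. MYH7, ODAM, FGF8 and SPACA1 had 0 counts over all 54 libraries together, PLG 2 and PRSS37 6. The siRNAs against MYH7, ODAM, FGF8 and SPACA1 changed 2719, 143, 445 and 576 genes against CTRL. Against the other siRNA groups they changed 2885, 501, 1156 and 613. The absence of counts argues against loss of the target transcript as the cause with these siRNAs, although a target could lie lower still. For each siRNA the 7-mer whose carriers, genes with it in their 3′ UTR, were lowest relative to other genes was sought; in 20 of 26 the 7-mer found in replicate 1 lay below all permuted genes in replicate 2 (lowest permuted z −5.46), and these included 3 of the 6, MYH7, SPACA1 and PRSS37, but not FGF8, ODAM or PLG. The 7-mer found from both replicates, chosen for its low z, which ran from −24.7 (GCCGTTT for IGF1R) to −5.53 (ACAAGAA for PLG), occurred in transcripts of the siRNA's own target for 22 of 26 siRNAs and 5 of the 6, against a mean of 7.35 and a highest of 16 in permuted pairings (one-sided permutation p = 1e-05, the smallest they can give). A candidate explanation for part of the changes is therefore repression through the guide strand's seed, which stays untested for every siRNA without the siRNA sequences. Medians over the 26 siRNAs of 19.3% of lower, 6.79% of higher and 12.1% of all genes carried the 7-mer, so that most lower genes lacked it. Of the 6, only MYH7 and PRSS37 met both criteria, and for PRSS37 17.5% of lower and 15.4% of higher genes carried it.

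The average siRNA group differed from CTRL, the group with the highest pseudogene share. With that share as a covariate, 130 genes other than pseudogenes were called instead of 975. For the 975, the median absolute log2 fold change went from 0.36 to 0.30 and the median SE from 0.09 to 0.12, so that the calls ended through both. This fit cannot tell a library axis apart from the siRNA effect. Its slope comes from differences between the 2 libraries of a group, while CTRL had the highest mean share. Single libraries overlapped, with 1.04% in GPR173 replicate 1 and 1.02% in CTRL replicate 1. Sites of 13 microRNA families had a mean z of 2.07 in this contrast, above all 10000 matched sets of 7-mers (median 0.0444), with miR-29 at 4.60 and miR-17 at 3.87. Relief of microRNA repression by transfected siRNA stays open, because CTRL also received siRNA, so that such relief would act there too, and the same z would arise from a deviation of the CTRL libraries themselves; against relief in siRNA groups as such, the mean z against the other groups was as low with ODAM (−2.24) as in CTRL (−2.07), and −1.68 with CMTM6. CTRL ranked 24 of 27 groups by genes differing from the others, and with 1 non-targeting group its own deviation cannot be told apart from an effect of targeting siRNA.

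Similar siRNA profiles lay close together in the deposited order of samples. Over 325 pairs of siRNA groups, profile r fell with distance in that order (Spearman rho −0.317, one-sided permutation p = 0.00014, 100000 permutations of the 26 groups), with a median r of 0.0787 for 25 neighbouring pairs and −0.104 for 136 pairs at least 10 apart. After pseudogene share and library total were regressed out rho was −0.275 (permutation p = 0.00052), which argues against depth and pseudogene share as the whole cause. A batch or handling order may underlie this, but the labels give no batch, the authors may have ordered the samples by other criteria, and a biological likeness of neighbouring targets was not tested.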
